A study of Mus musculus with 12 samples.

How the data were processed

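RNA from 12 cultures of mouse embryonic fibroblasts was labelled with biotin from 100 ng of total RNA and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The labels give 12 combinations of SKO (yes or no), virus (blank control, cluster B or cluster C) and day (4 or 8), with 1 array each. Feeder cells had been removed before extraction, per the labels' protocols.

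The deposited table holds log2 values of 28853 probe sets on the 12 arrays. RMA, which corrects background, normalizes between arrays and summarises probes, and Partek are named in the submitters' processing notes, without versions or roles. The log2 scale was read from the deposited values, which run from 0.916 to 14.034. The genome build and the authors' probe set annotation are not given in the sources used here. No value was missing. The smallest mean absolute difference between 2 arrays was 0.167, so no array was a copy of another. Values after RMA carry no counts, so the number of arrays is what limits precision. Lower quartiles of the arrays lay between 3.48 and 3.68, and a difference from a value below that is best read as a lower bound. RMA pulls the arrays to a common distribution, and a change shared by most genes would not be seen.

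Probe sets were named through the platform annotation, in which 21789 had 1 gene, 1621 several and 5443 none. Symbols were compared with RefSeq of GRCm38.p6 through Entrez identifiers, of which 21698 matched and 0 changed. Probe sets with several genes or none were left out of the main tests. Where a gene had several probe sets, which held for 999 genes, the one with the highest mean was kept, giving 19938 genes. The Y-linked and X-inactivation genes were read as a check on the make-up of the cell pools.

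Genes were tested with limma 3.58.1 in R 4.3.3. One fit over all 12 arrays had 8 coefficients, for SKO, day, cluster and the interactions of SKO with day and with cluster, which left 4 residual degrees of freedom, and empirical Bayes added 4.94 prior ones. The residual spread (median SD 0.152 in log2 units) is the amount by which cluster effects differ between days, so an effect present on 1 day counts as error. Nothing says that arrays came from separate experiments, and p-values measure that spread alone. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 per comparison. In total 13 comparisons were made. Gene lists were tested with limma's camera at the preset correlation of 0.01 and again with an estimated one, over 21 lists adjusted per comparison. The lists held 655 genes, of which 606 were measured, on cell identity, cell cycle, signalling, metabolism and other cell types. Single differences between 2 arrays were set against 10000 random lists with similar mean expression, as a description of those arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

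The fit, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for clusters against blank virus with SKO and for SKO at day 8, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in every matched pair, and 5 and 5 in the other comparisons. Where fewer pass, places are filled by genes with the largest change of the same sign in every pair, said to have missed the threshold. Predicted and clone names, receptor families and small RNA genes are left out. Up to 2 highest and 2 lowest members of a described list are also named, with the delivered factors and Myc.

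The fit was tested on simulated data for 19938 genes, of which 200 were changed. Each simulated change was the same at both days, with noise independent between arrays. The shares recovered therefore do not hold for an effect present on 1 day, which the fit counts as error. For cluster C against blank virus with SKO it recovered 6.8% of genes changed by 0.58 log2 units, 70% at 1, 98% at 2 and 100% at 3, with 4.2% false calls. For SKO at day 8 it recovered 32%, 84%, 99.2% and 100%, with 5.6% false calls.

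Alternatives were each arm fitted alone, an additive fit, a mean-variance trend with robust empirical Bayes, quantile normalization, equal array medians, a filter on dim genes, the mean over probe sets, every probe set, a minimum change of 1.5-fold and leaving out each array in turn. A test of microRNA seed sites in 3' untranslated regions was planned and not run, since transcript sequences were not used here.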

Results

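Gene expression was measured on 12 whole-transcript microarrays of mouse embryonic fibroblasts. Viruses were used to deliver a microRNA cluster, called B or C in the labels, or a blank control virus. Cells of 1 arm also received SKO, taken here as the reprogramming factors Sox2, Klf4 and Oct4 (the product of Pou5f1), which can turn fibroblasts into induced pluripotent stem cells; the labels do not spell the letters out. The other arm received no SKO. Titles of all its arrays carry the tag Group2, which the titles do not explain, and no title of the arm with SKO does. Differences between the arms therefore cannot be told apart from differences between these groups. RNA was taken 4 and 8 days after the first infection, in mouse embryonic stem cell medium. Each of the 12 combinations of SKO, virus and day had 1 array, so no condition had a replicate, and the number of arrays limits the precision of every value. Errors given as SE come from a limma fit over all 12 arrays, in which the spread is the amount by which a cluster effect differed between the days and a day effect between the viruses. Deposited log2 values had medians between 4.98 and 5.07 on the 12 arrays. The first principal component held 64.3% of the variance of the brighter genes and separated arrays with SKO from those without, and the second held 16.9% and separated the days.

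The delivered genes were read on every array as a check of the labels. Pou5f1 lay at 11.60 or above on the 6 arrays with SKO and between 3.35 and 4.56 on the 6 without. Klf4 lay between 8.63 and 8.91 with SKO and between 6.92 and 7.16 without. Sox2 was at 5.34 to 6.04 on 5 of the arrays with SKO, at 7.55 on the array with SKO and cluster C at day 8, and at 4.55 to 5.18 without SKO. Its difference at day 4 was 0.76 (limma adjusted p = 0.116), and whether its probe set reads delivered Sox2 as well as the cells' own is not known here, so it does not check the labels. Myc, which SKO does not include, was at 7.98 to 8.37 with SKO and at 6.62 to 7.62 without. The X-inactivation transcript Xist was at 7.14 to 7.55 on the 12 arrays, and the Y-linked Eif2s3y at 6.26 to 7.08, Kdm5d at 5.14 to 5.96 and Uty at 5.23 to 6.43. Uty was higher with SKO at day 8 (0.66, limma adjusted p = 0.0154) and fell from day 4 to day 8 without SKO (-0.78, adjusted p = 0.0207), where Kdm5d differed by -0.54 (adjusted p = 0.0895). Ddx3y was not analysed here.

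The labels do not say which microRNAs the clusters hold, so microRNA probe sets were examined after their values were seen. Whether these probe sets read mature microRNAs or longer transcripts that hold them is not known here. Mir302b was at 7.08 and 7.15 on the arrays with SKO and cluster C, and at 5.82 at day 4 and 2.86 at day 8 with cluster C and no SKO. On the 8 arrays without cluster C it did not exceed 2.32. Mir302a, Mir302c, Mir302d and Mir367, neighbours of Mir302b on chromosome 3, were likewise highest on the arrays with SKO and cluster C. Mir363 was at 5.36 and 5.13 with SKO and cluster B, at 3.98 and 3.08 with cluster B and no SKO, and at most 2.63 on the other 8 arrays. Mir106a and Mir20b, which lie with Mir363 on the X chromosome, were at 3.77 and 4.12 with SKO and cluster B at day 4, against 2.09 and 2.51 with SKO and blank virus.

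**Figure D1:**
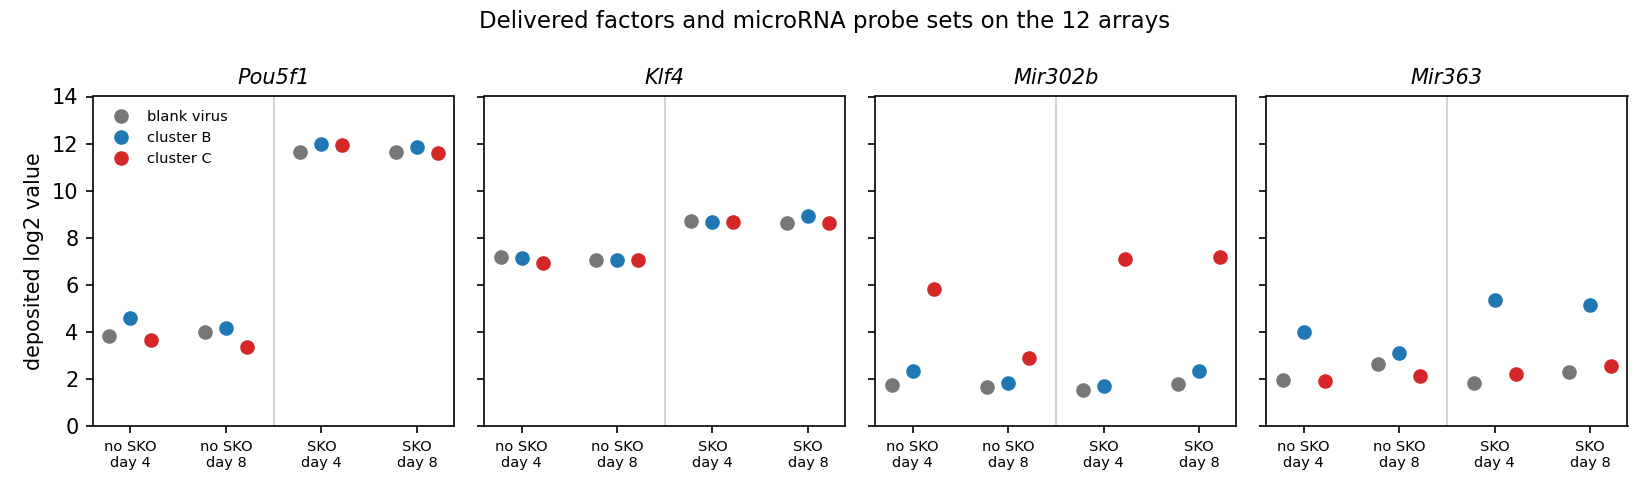
Deposited log2 values of Pou5f1, Klf4, Mir302b and Mir363 on each of the 12 arrays, with SKO and day on the horizontal axis and colour giving the virus; each point is 1 array. Pou5f1 is at 11.60 or above on every array with SKO, and Mir302b is at 7.08 and 7.15 with SKO and cluster C.

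The first question was what cluster C changed in fibroblasts undergoing reprogramming, relative to blank virus. With SKO, the probe sets that rose were those of the microRNAs themselves: Mir302b by 5.48 ± 0.54 on the log2 scale (SE, 2 arrays against 2; limma adjusted p = 0.0213), Mir302a by 3.80 and Mir367 by 2.91. With blank virus Mir302b was at 1.51 and 1.77, under the lower quartile of those arrays, so its difference is best read as a lower bound. The olfactory receptor gene Olfr354 fell by 1.18. These 4 lie outside the rule for named genes and were named after their values were seen. Among 19938 genes tested, no other gene passed an adjusted p of 0.05, and 1359 had an unadjusted p under 0.05. If no gene changed, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. Such counts, here and below, are therefore not counts of effects. The rule for named genes, which leaves out small RNA genes, gave Tdgf1, a Nodal co-receptor of pluripotent cells (1.92 ± 0.65, adjusted p = 0.687), Nr0b1, an orphan nuclear receptor of embryonic stem cells (1.82 ± 0.43), Bex1 (1.74), Zfp600 (1.31), carbonic anhydrase gene Car2 (1.24), H2bc9 (1.13), Laptm5 (1.09), the tight junction gene Cldn4 (1.05), the glucose transporter gene Slc2a3 (1.05) and Ankrd45 (1.04). On the lower side were Teddm3 (-1.51, adjusted p = 0.0799), Cdnf (-1.03), Kcnj14 (-1.02), Ccr9 (-0.93), Angptl7 (-0.91), Dcpp3 (-0.88), H2-Q5 (-0.81), Lce3f (-0.80), Fam217a (-0.80) and Smad9 (-0.78). All 20 missed the threshold. Several rest on 1 day, with differences at day 4 and day 8 of 0.09 and 3.76 for Tdgf1, 0.09 and 2.01 for Slc2a3, -1.89 and -0.15 for Kcnj14, -1.63 and -0.12 for Dcpp3, -1.46 and -0.15 for Lce3f and -0.01 and -1.62 for H2-Q5.

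Gene lists fixed beforehand showed shifts that single genes did not. With SKO and cluster C, 30 of the 32 measured collagen and extracellular matrix genes lay below blank virus, with a median log2 difference of -0.36. None passed over all genes, and 19 fell when p was adjusted over the list alone, with Col11a1 (-0.65) and Ogn (-0.61) lowest and Mfap4 (0.13) highest. The list passed limma's camera test at the preset correlation (adjusted p = 1.51e-16), with adjusted p = 0.177 with an estimated correlation. The median was -0.34 at day 4 and -0.30 at day 8, and all of 12 fits that left out 1 array kept the call, with medians from -0.38 to -0.29. Leaving out an array without SKO cannot change this estimate, and these fits used the preset correlation. The mesenchymal list, 30 of 32 genes below 0 with a median of -0.20, included the PDGF receptor genes Pdgfrb (-0.44) and Pdgfra (-0.43). Its adjusted p was 1.14e-07 at the preset correlation and 0.177 with an estimated correlation. Pluripotency genes that were not delivered lay higher (26 of 29 above 0, median 0.49, adjusted p = 1.93e-14), with 4 that rose when adjusted over the list alone. The highest were Tdgf1 and Nr0b1 and the lowest Zfp42 (-0.24) and Dppa3 (-0.07). With an estimated correlation the adjusted p of this list was also 0.177. Epithelial genes lay higher too (38 of 44 above 0, median 0.26, adjusted p = 7.74e-11, and adjusted p = 0.177 with an estimated correlation), among them the adhesion gene Cdh1 (0.76 ± 0.13, adjusted p = 0.34) and Cldn4, with 3 past the threshold over the list alone. The epithelial median was 0.02 at day 4 and 0.43 at day 8.

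Of the remaining 17 lists, 8 passed at the preset correlation. The G1/S and DNA replication list (34 of 35 above 0, median 0.21, adjusted p = 1.38e-06) included Gins1 (0.41) and Mcm5 (0.40), and the G2/M list (31 of 35, median 0.13, adjusted p = 0.000439) included Bub1 (0.44) and Aurka (0.39). Their adjusted p values with an estimated correlation were 0.429 and 0.572. Without the day 8 array of SKO and cluster C these medians turned to -0.01 and -0.15. Smaller medians were found for keratinocyte genes (0.15, adjusted p = 0.00329), cholesterol biosynthesis (-0.13, adjusted p = 0.00616), leukocyte genes (-0.19, adjusted p = 0.0261), muscle genes (-0.13, adjusted p = 0.0261), p53 pathway genes (0.11, adjusted p = 0.0432) and TGF-beta signalling (-0.10, adjusted p = 0.0432). Between single arrays of the same day, the keratinocyte median was -0.03 at day 4 and 0.43 at day 8. In a fit with the cluster C effect free to differ between days, it was 0.06 at day 4 and 0.24 at day 8. By that fit the p53 median was 0.05 at day 4 and 0.15 at day 8. The TGF-beta median was -0.05 and -0.12. Leaving out 1 array turned the keratinocyte median to -0.06 and the muscle median to 0.02. With an estimated correlation no list passed after adjustment, and 5 had an unadjusted p under 0.05. Reported targets of microRNAs with the AAGUGC seed, which Mir302 family members carry, had a median of -0.09 over 44 genes (adjusted p = 0.114).

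The pluripotency difference, like the epithelial and keratinocyte ones, lay mainly in 1 array. At day 8 the median of the list was 0.77 above blank virus, higher than each of 10000 random lists of like expression (95% of them between -0.13 and 0.10), and at day 4 it was 0.08. Dppa5a, a marker of pluripotent cells, was at 10.22 on the array with SKO and cluster C at day 8, at 6.61 with SKO and blank virus and at 6.82 with SKO and cluster B. Tdgf1 was at 9.37 against 5.61 and 6.18, and Nanog, a core pluripotency factor, at 8.08 against 6.34 and 6.39. A fit in which the cluster C effect could differ between the days was chosen after this array was seen to stand out. It sets 1 array against 1 at each day, so its SE and adjusted p take their spread from the other conditions (3 residual degrees of freedom) and hold no spread of this condition. It called 17 genes higher and 1 lower at day 8 and 0 at day 4, where 1318 genes had an unadjusted p under 0.05. Among those higher were Dppa5a (3.54 ± 0.29, limma adjusted p = 0.0192), Tdgf1 (3.47), Nr0b1 (2.86), Dppa2 (2.03), the methyltransferase cofactor gene Dnmt3l (1.78), Sox2 (1.70) and the zinc finger gene Sall4 (1.61). Nanog (1.72 ± 0.33) had an adjusted p of 0.321. The difference between the days was itself tested and called 0 genes, with 1259 at an unadjusted p under 0.05. In the main comparison, 4 genes became 18 without the array with SKO and cluster C at day 4, which leaves the same contrast at day 8, and 0 without either array of SKO and blank virus, of SKO and cluster B, or of cluster B without SKO, or without SKO and cluster C at day 8.

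**Figure D2:**
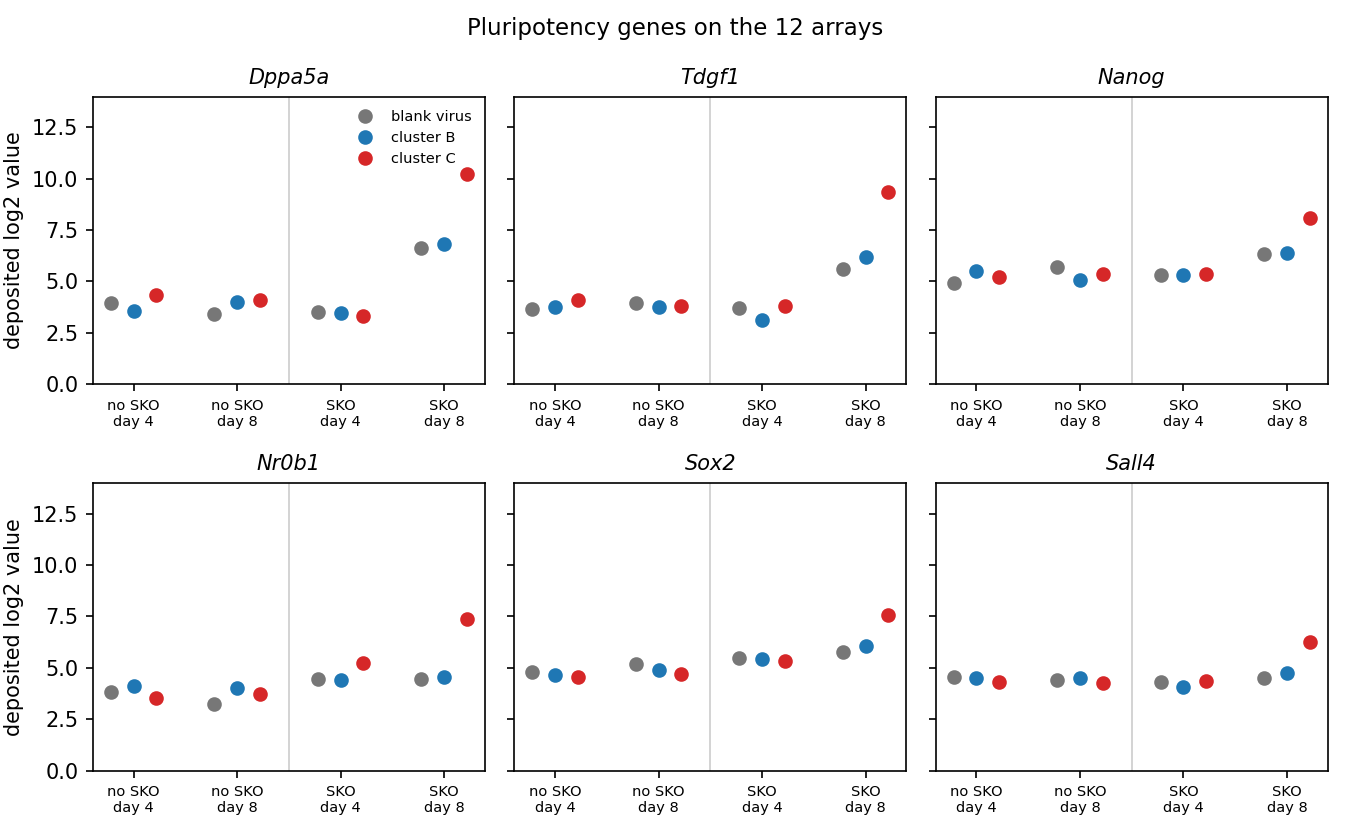
Deposited log2 values of Dppa5a, Tdgf1, Nanog, Nr0b1, Sox2 and Sall4 on each of the 12 arrays, with SKO and day on the horizontal axis and colour giving the virus; each point is 1 array. The array with SKO and cluster C at day 8 is the highest in each panel, with Dppa5a at 10.22 against 6.61 with blank virus.

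Cluster B was compared with blank virus in the same way. With SKO, Mir363 rose by 3.20 ± 0.32 (limma adjusted p = 0.0353) and Olfr354 fell by 1.55 (adjusted p = 0.0143), both named after their values were seen. No other gene passed, and 614 had an unadjusted p under 0.05. The rule for named genes put Tomm5 first (1.0 ± 0.52), though its differences were 0.01 at day 4 and 1.99 at day 8 and leaving out 1 array turned the estimate to -0.04. Next came Chml (0.97), the cornified envelope gene Sprr2f (0.86), Neurod4 (0.81), Pcdhb11 (0.78), Aim2 (0.77), Fundc1 (0.77), the histone genes H2bc3 (0.73) and H1f1 (0.71) and Sprr1a (0.69). On the other side were Teddm3 (-1.23 ± 0.19, adjusted p = 0.667), Gpx2 (-0.88), Sbpl (-0.78), Pramel19 (-0.77), Tuba3b (-0.76), Wfikkn2 (-0.67), Pramel13 (-0.67), Ifi205 (-0.67), Lrrc75b (-0.66) and Dnaaf6 (-0.65). All 20 missed the threshold. The calls were lost without any 1 of several arrays, among them both arrays with SKO and blank virus. Olfr354 (-1.18) and Teddm3 (-1.51) were lower with cluster C too, against the same blank virus arrays, and neither passed between the clusters. High values on those arrays cannot be told apart from an effect of both clusters.

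With SKO and cluster B, 7 of 21 lists passed at the preset correlation and 0 with an estimated one. Collagen and matrix genes lay lower, with a median of -0.11 and 29 of 32 below 0 (adjusted p = 7.11e-05, and adjusted p = 0.475 with an estimated correlation), among them Col11a1 (-0.33) and Col1a2 (-0.28). In a fit with the cluster B effect free to differ between days, the matrix median was -0.18 at day 4 and -0.06 at day 8. Interferon response genes, the antiviral program, had a median of -0.23 (adjusted p = 0.0023, and adjusted p = 0.75 with an estimated correlation), with Ifit1 at -0.67 and Oasl2 at -0.56. The days went opposite ways, with a median between single arrays of -0.67 at day 4 and 0.29 at day 8. The G1/S and G2/M lists had medians of 0.13 and 0.08 (adjusted p = 0.0023 and 0.032), which turned to -0.03 and -0.11 without the day 4 array of SKO and cluster B. Endothelial (-0.12), keratinocyte (0.08) and ribosomal protein genes (0.06) also passed, and the keratinocyte median turned to -0.06 without the day 8 array of SKO and blank virus. In the fit free to differ between days, the median was -0.15 at day 4 and -0.02 at day 8 for endothelial genes, and 0.09 and 0.03 for ribosomal protein genes. The pluripotency list did not pass, with a median of -0.02 (adjusted p = 0.96), nor did the epithelial list (0.05, adjusted p = 0.177).

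The clusters were then set against each other. With SKO, cluster C exceeded cluster B in Mir302b (5.12 ± 0.54, limma adjusted p = 0.0376), Mir302a (3.46) and Mir367 (2.95), and Mir363 was lower by the same test (-2.88, adjusted p = 0.0414). No other gene passed, and 1102 had an unadjusted p under 0.05. Among genes chosen by the rule, Tdgf1 (1.94 ± 0.65), Nr0b1 (1.82), Bex1 (1.35), Zfp600 (1.28) and Zfp640 (1.24) were higher with cluster C, and Tomm5 (-1.22), Lce3f (-0.96), Ctla2a (-0.80), P2ry10b (-0.77) and Cdnf (-0.74) were higher with cluster B, all short of the threshold. Zfp600 differed by 0.07 at day 4 and 2.5 at day 8, and Zfp640 by 0.18 and 2.3. The pluripotency list (28 of 29 above 0, median 0.53, adjusted p = 4.74e-15), the epithelial list (median 0.22, adjusted p = 2.14e-08), the matrix list (median -0.19, adjusted p = 2.14e-08) and the mesenchymal list (median -0.18, adjusted p = 9.27e-07) passed at the preset correlation. Each had an adjusted p of 0.236 with an estimated correlation. The pluripotency and epithelial differences were larger at day 8. Against the mean of all arrays, the pluripotency median with clusters C and B was 1.09 and 0.05 at day 8, and -0.13 and -0.33 at day 4. The epithelial median was 0.85 and 0.39 at day 8, and -0.04 and -0.15 at day 4. The gene count was 13 without the array of SKO and cluster C at day 4, and 0 without any other array with SKO.

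**Figure D3:**
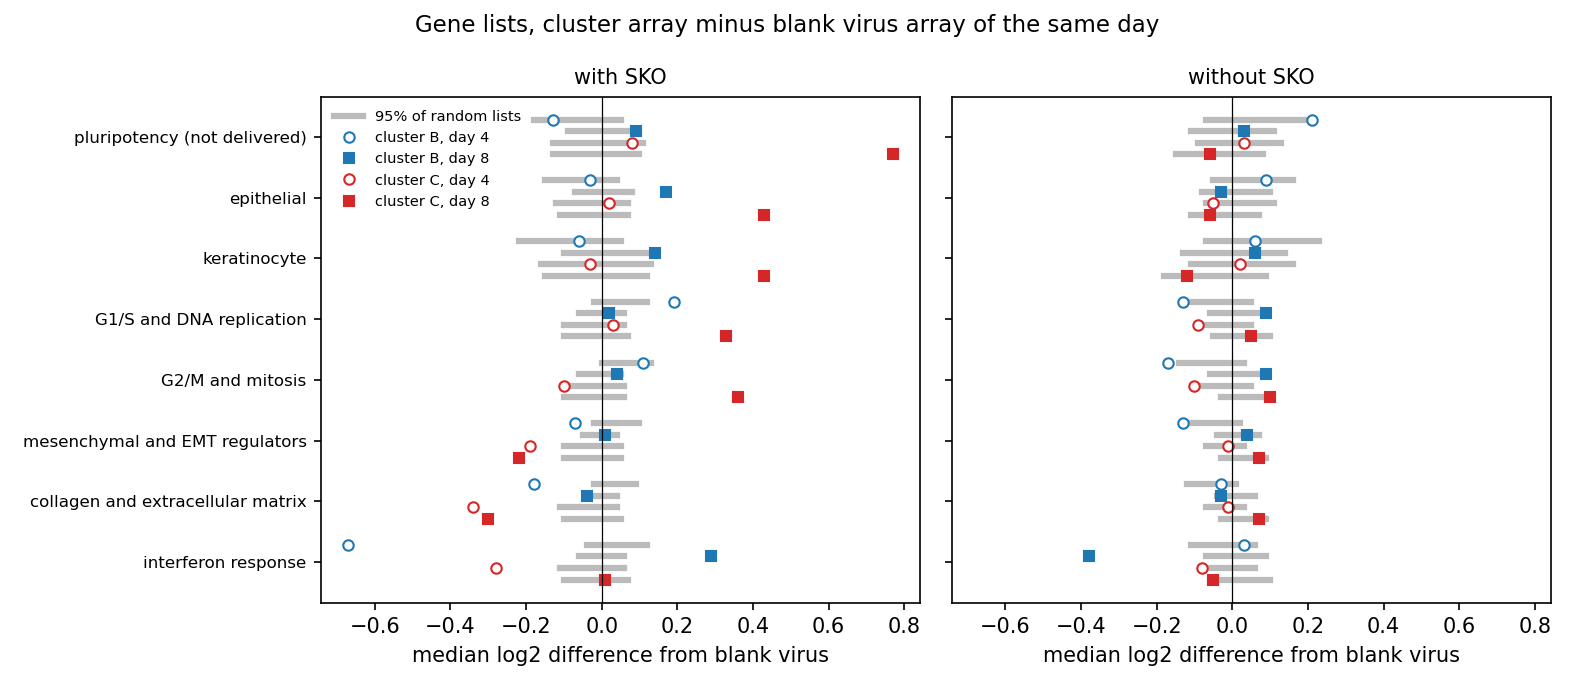
Median log2 difference of 8 gene lists between a cluster array and the blank virus array of the same day, with SKO on the left and without SKO on the right. Open circles are day 4, filled squares day 8, and grey bars hold 95% of 10000 random lists of like mean expression; with SKO and cluster C the pluripotency list is at 0.77 at day 8 and 0.08 at day 4.

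In fibroblasts without SKO, the same comparisons asked what each cluster did on its own. With their clusters, Mir302b and Mir363 were lower there than with SKO, so a weaker cluster effect cannot be told apart from less microRNA signal. No gene passed for cluster B, cluster C or their difference with limma, and 1169, 941 and 1260 genes had an unadjusted p under 0.05. With no change in any gene, a share of about 0.05 of those tested would have such a p. Mir302b was at 2.65 with cluster C (adjusted p = 0.866) and at 2.29 between the clusters, and Mir363 at 1.24 with cluster B (adjusted p = 0.761) and at -1.51 between the clusters. With small RNA genes left out by the rule, the genes named for cluster B were H2bc9 (1.42), the lens crystallin gene Crygs (1.27 ± 0.14, adjusted p = 0.149), Insm1 (1.05), Cdc26 (1.04) and Mycs (0.97), and Krtap19-4 (-0.97), Mrgprb13 (-0.96), Csdc2 (-0.95), Chml (-0.93) and Zfp931 (-0.91). With cluster C they were Spata31 (1.07), Ppp3r2 (0.85), H2bc9 (0.80), Cyp4a12a (0.80) and Ccer1 (0.80), and Cebpzos (-1.08), Aard (-1.06), Mir17hg (-1.03), Ifi214 (-1.03) and Sh2d1b2 (-1.0). Between the clusters they were Ifna14 (1.27), Mrgprb13 (1.20), Senp8 (1.12), the chemokine gene Ccl12 (1.05) and Slc22a30 (0.97), and Myct1 (-1.03), Crygs (-1.02), Ccin (-1.01), Teddm3 (-0.95) and Mycs (-0.90). None of these 30 values passed. Interferon genes had a median of -0.15 with cluster B (adjusted p = 0.00356, and adjusted p = 0.885 with an estimated correlation). It was 0.03 at day 4 and -0.38 at day 8, and the call was lost without the day 8 array of cluster B. No other list passed in any of the 3 comparisons. Pluripotency genes had medians of 0.14 with cluster B and 0.02 with cluster C, and matrix genes -0.01 and 0.05. Without the day 8 array of cluster C, cluster C called 3 genes and the comparison of the clusters 2.

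Whether a cluster acted differently with SKO was tested as an interaction. The microRNA signal itself differed between the arms. With cluster C, Mir302b was at 7.08 and 7.15 with SKO, and at 5.82 and 2.86 without. A different action of a cluster therefore cannot be told apart from a difference in the signal of its microRNA probe sets. No gene passed for cluster B or cluster C with limma, and 1036 and 1155 had an unadjusted p under 0.05. Small RNA genes, left out by the rule, differed more, with Mir363 at 1.96 ± 0.45 for cluster B (adjusted p = 0.919) and Mir302b at 2.83, Mir302a at 2.43 and Mir302c at 2.30 for cluster C. The genes named by the rule for cluster B were Chml (1.90), Tomm5 (1.59), Zfp931 (1.36), Csdc2 (1.32) and H2ac4 (1.25), and Teddm3 (-1.83 ± 0.26, adjusted p = 0.453), Crygs (-1.47), H2bc9 (-1.33), Ppp3r2 (-1.30) and Actl11 (-1.28). For cluster C they were Mir17hg (2.02), Ifi214 (1.96), Nr0b1 (1.72), Sh2d1b2 (1.72) and Fbxo15 (1.46), and Kcnj14 (-1.47), Wfikkn2 (-1.25), Ccer1 (-1.23), Teddm3 (-1.16) and C4b (-1.15). For cluster C, 10 lists passed at the preset correlation. The cluster C effect on the matrix list was lower with SKO than without, by a median of 0.35 in log2 units (median difference -0.35, 31 of 32 below 0, adjusted p = 3.94e-14). Its effect on the pluripotency list was higher with SKO than without (median 0.48, 29 of 29 above 0, adjusted p = 8.98e-09). The same held for its effect on the epithelial list (median 0.33, adjusted p = 2.68e-08). Each of these 3 had an adjusted p of 0.257 with an estimated correlation. The pluripotency and epithelial differences lay mainly on the array with SKO and cluster C at day 8. Medians against the mean of all arrays were 1.09 and 0.85 there, and 0.05 and 0.24 with SKO and blank virus. At day 4 they were -0.13 and -0.04 with SKO and cluster C, and -0.09 and -0.11 with SKO and blank virus. For cluster B the G1/S list passed (median 0.13, adjusted p = 0.0243, and adjusted p = 0.938 with an estimated correlation). Without the day 4 array of cluster C and no SKO, 5 genes passed for cluster C.

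The next comparison set the arm with SKO against the arm without it, averaged over the 3 viruses. As the titles also mark the arms as separate groups, the differences cannot be credited to SKO alone. At day 8, 2674 genes were higher and 2525 lower with SKO, 718 and 424 of them by at least 2-fold. Besides the delivered Pou5f1 (7.86 ± 0.13, limma adjusted p = 1.05e-08, 3 of 3 pairs), the largest rises were in the dipeptidyl peptidase gene Dpp4 (5.73 ± 0.14, 53.2-fold), the aspartoacylase gene Aspa (5.65), the aldehyde dehydrogenase gene Aldh3a1 (5.52), the thyrotropin-releasing hormone gene Trh (4.78), Gna14 (4.71), Fetub (4.6), the adhesion molecule gene Ceacam1 (4.46), Fbxo15, an Oct4 target in embryonic stem cells (4.35), and Cth, of cysteine synthesis (4.08). The largest falls were in Abi3bp (-3.98 ± 0.14), the small leucine-rich proteoglycan genes Epyc (-3.96), Kera (-3.19) and Lum (-3.01), dermatopontin gene Dpt (-3.82), the chemokine genes Cxcl15 (-3.85) and Ppbp (-3.08), Igfbp2 (-3.48), the kinase gene Nrk (-3.22) and the bradykinin receptor gene Bdkrb1 (-2.95).

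By list, epithelial genes rose with SKO at day 8: 28 of 44 were higher, 1 lower and 15 not past the threshold, with a median of 0.62. Epcam rose by 3.49 and the desmosome gene Dsp by 2.82, and P-cadherin gene Cdh3 fell by 2.11. Keratinocyte genes were higher in 12 of 23 and lower in 2, with Krt14 at 2.42 and Lgals7 at 2.37, and Lor at -0.98. Matrix genes fell in 25 of 32 and rose in 2, among them Lum (-3.01) and Mfap4 (-2.66), against Timp3 (0.96) and Eln (0.56). Mesenchymal genes fell in 21 of 32, with Postn at -2.64 and Lox at -1.62, and rose in 4, with Meox2 at 1.94. Pluripotency genes rose in 12 of 29, with Fbxo15 at 4.35 and Dppa5a at 4.04, and fell in 2, Klf2 (-0.79) and Klf5 (-0.42). Their median was 1.33 in the pair with cluster C, and 0.12 and 0.10 in those with blank virus and cluster B. Glycolysis genes rose in 8 of 19, with Aldoc at 2.96 and Slc2a3 at 2.37, and leukocyte genes fell in 16 of 25, with Lyz2 at -1.30. Camera's adjusted p at the preset correlation was 3.08e-13 for the epithelial and 1.45e-12 for the matrix list, and 11 of 21 lists passed. With an estimated correlation none passed, and the adjusted p of both was 0.204. Leaving out the blank virus or the cluster C array with SKO at day 8 lowered the total of 5199 genes to 3145 and 3378.

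**Figure D4:**
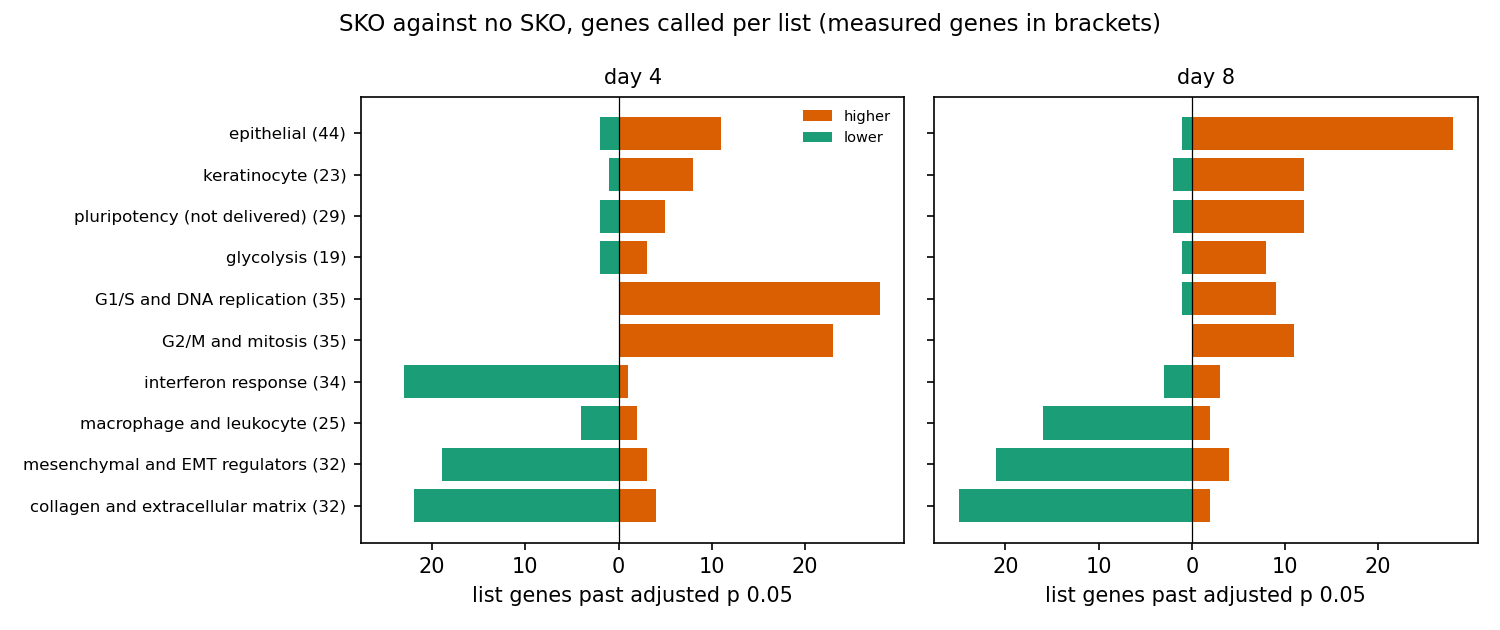
Number of genes higher (right of 0) and lower (left of 0) with SKO than without it at an adjusted p under 0.05, for 10 gene lists at day 4 and day 8, with the measured genes of each list in brackets. At day 8, 28 of 44 epithelial genes are higher and 25 of 32 matrix genes lower.

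At day 4, 1899 genes were higher and 1874 lower with SKO. Pou5f1 (7.85 ± 0.13, limma adjusted p = 1.06e-08, 3 of 3 pairs), the steroid-metabolising Akr1c18 (5.78), Aldh3a1 (5.44), Gna14 (4.28) and Sostdc1 (4.18) rose most, and the interferon-induced Ifit3 (-2.97) and Cxcl10 (-2.55), the chemokine gene Cxcl12 (-2.93), Ogn (-2.59) and Rspo2 (-2.57) fell most. DNA replication genes rose in 28 of 35 and fell in 0, with Rrm2 at 1.44 and Mcm6 at 1.04, and G2/M genes rose in 23 of 35, with Nusap1 at 1.15. Interferon genes fell in 23 of 34, and Oas2 rose by 1.90. Matrix genes fell in 22 of 32 and mesenchymal genes in 19 of 32, with Pdgfra at -2.19 and Lox at -1.84. Epithelial genes rose in 11 of 44 and fell in 2, with a median of 0.03. At the preset correlation 13 lists passed, with adjusted p = 3.32e-17 for DNA replication and 2.29e-09 for interferon genes. With an estimated correlation none passed, and these 2 had adjusted p = 0.23 and 0.384. In 1354 genes the rise was called at both days, against 255 for independent lists, and in 1184 the fall, against 237, while 46 genes were called in opposite directions. Both days compare the same arms in the same fit, with a shared residual spread for each gene. More overlap than for independent lists was therefore likely from the outset. The total of 3773 genes fell to between 2178 and 2485 without the day 4 arrays of SKO with blank virus, SKO with cluster B, cluster B alone or cluster C alone.

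The time course was read as day 8 against day 4. With SKO, 1045 genes rose and 730 fell. Dppa5a rose by 4.44 ± 0.61 (limma adjusted p = 0.00291, 3 of 3 pairs), Tdgf1 by 3.49, the acute-phase gene Saa3 by 3.31, the kallikrein gene Klk1b5 by 2.88 and the tachykinin gene Tac2 by 2.78. The pairs with blank virus, cluster B and cluster C gave 3.08, 3.33 and 6.91 for Dppa5a, which at day 4 was at most 3.53, near the lower quartile of the arrays, and 1.88, 3.04 and 5.55 for Tdgf1, so the cluster C pair raised both means. Akr1c18 (-3.06), Rgs5 (-1.98), Npy2r (-1.34), the serine synthesis gene Phgdh (-1.23) and Fbn2 (-1.22) fell most. Epithelial genes rose in 23 of 44 and fell in 0, with Epcam at 2.31 and Krt19 at 1.89. Glycolysis genes rose in 11 of 19, with Bnip3 at 2.44 and Aldoc at 2.41. Keratinocyte genes rose in 10 of 23 and pluripotency genes in 8 of 29. G2/M genes fell in 23 of 35, with Cenpe at -1.04 and Racgap1 at -1.01, and DNA replication genes in 19 of 35. The adjusted p at the preset correlation was 1.1e-20 for G2/M and 7.31e-20 for epithelial genes, and 0.229 and 0.123 with an estimated correlation. The total of 1775 genes was between 655 and 949 without any 1 of the 6 arrays with SKO.

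Without SKO, 807 genes rose from day 4 to day 8 and 923 fell. The matrix genes Epyc (3.27 ± 0.14, limma adjusted p = 9.85e-06, 3 of 3 pairs), Comp (2.84) and Kera (2.72), the growth factor gene Igf1 (3.05) and Lbp (2.87) rose most, and the interferon-induced Ifit3 (-2.18), Ifit3b (-2.01), Cxcl10 (-1.96) and Mx2 (-1.67) and Gpnmb (-1.77) fell most. Matrix genes rose in 13 of 32 and fell in 0, with Eln at 2.58 and Mfap4 at 2.31. Interferon genes fell in 13 of 34, and Ifi27 rose by 1.15. G2/M genes fell in 14 of 35, with Kif20a at -0.76, and leukocyte genes rose in 7 of 25, with Mrc1 at 1.10. The adjusted p at the preset correlation was 1.71e-11 for matrix and 6.62e-11 for interferon genes, and 0.258 and 0.359 with an estimated correlation. The total of 1730 genes was between 534 and 639 without any 1 of the 6 arrays lacking SKO.

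The 2 time courses differed in 592 genes by the interaction test, 392 with a day effect that was more positive with SKO and 200 with one more negative. Dppa5a (4.55 ± 0.86, limma adjusted p = 0.0284), the ectonucleotidase gene Enpp3 (3.57), Tdgf1 (3.50, adjusted p = 0.0434), Angptl7 (3.02) and Saa3 (3.01) lay at one end, and Epyc (-3.27 ± 0.20), Kera (-2.99), Akr1c18 (-2.59), Ccn3 (-2.40) and Dpt (-2.34) at the other. By virus, Dppa5a gave 3.62, 2.88 and 7.15 and Tdgf1 1.57, 3.07 and 5.86 with blank virus, cluster B and cluster C, so cluster C raised these means too. In the epithelial list 12 of 44 genes had a more positive day effect with SKO and 0 a more negative one, with Epcam at 2.47 and Krt7 at 1.94. In the matrix list 7 of 32 had a more negative one, with Lum at -1.71 and Mfap4 at -1.62, and 1 a more positive one. The adjusted p at the preset correlation was 2.46e-17 for epithelial and 2.95e-06 for matrix genes, and 0.25 and 0.277 with an estimated correlation. The count of 592 was between 230 and 306 without any 1 of the 12 arrays.

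How far a cluster effect recurred was read from correlations across genes between differences that share no array. Genes are not independent replicates, and no p is given. Over the brighter genes, the cluster C difference with SKO at day 4 correlated with that at day 8 at 0.190, and the cluster B difference at -0.032. Without SKO the values were 0.019 and -0.055. The difference of cluster B at day 4 correlated with that of cluster C at day 8 at 0.181 with SKO and at -0.190 without, and that of cluster B at day 8 with that of cluster C at day 4 at 0.030 and 0.056. Differences of B and C on the same day share a blank virus array, and correlated at 0.457 and 0.434 with SKO, where simulated arrays with no effect gave 0.498. Their covariances of 0.0213 and 0.0162 compare with 0.022 in the simulation.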

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

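All tests of explanations in this part were written after the pattern was seen, except the first on other microRNA probe sets, and several were changed again after a first value was known. The scaling test first used quantile normalization and was replaced by random lists. Falling genes were added to the test on an advance along the time course and are given as values. The bound on bright microRNA probe sets and the bootstrap range for the interferon share were added, the swapped label was divided by partner array, and both interferon tests were moved to undecided. No condition had 4 or more arrays, so no single array was tested for lying apart from its group.

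The change from day 4 to day 8 differed between arrays with and without SKO in 592 genes by the interaction test. The differences in log2 units were 4.55 for Dppa5a, 3.57 for Enpp3, 3.50 for Tdgf1, 3.02 for Angptl7 and 3.01 for Saa3, and -3.27 for Epyc, -2.99 for Kera, -2.59 for Akr1c18, -2.40 for Ccn3 and -2.34 for Dpt. Cluster C carried much of the Dppa5a and Tdgf1 values, with 7.15 and 5.86 against 3.62 and 1.57 for blank virus. Among the 7064 probe sets without a single gene name, which the comparisons left out, 375 were higher with SKO at day 8 and 409 lower, 140 of them higher by at least 2-fold.

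The comparisons of 3 arrays with 3 allow 10 splits of the 6 arrays, too few for a share under 0.05. In fits of 2 groups alone, the real split called 3326 genes for SKO at day 4, 5708 for SKO at day 8, 1644 for the day with SKO and 1673 for the day without SKO. In each of these 4 cases it was the 1 split with that many genes, and the highest of the other splits called 0. Every other split mixes the real groups, which puts their difference into its residual spread. Low counts there were likely from the outset, so these counts decide nothing.

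Higher pluripotency genes on the array with SKO and cluster C at day 8 were weighed first. A scaling of the whole array would move random lists of like expression as far, and the list lay at percentile 100 of 10000 of them, with a median of 0.77 that was 0.73 after quantile normalization. A label swapped with an array lacking cluster C would remove the microRNA signal, and Mir302b on this array exceeded the highest such array by 4.83; a swap with the day 4 array of cluster C would reverse the 100 genes falling most in the other SKO arrays, and 93 of them were lower at day 8, with a median of -0.58. An advance along the time course of the cluster B arrays stays open: the 100 genes rising most there had a median of 0.04 (percentile 97.1), and epithelial (0.43) and keratinocyte genes (0.43), which rise with time, were higher, while the 100 falling most were higher too (0.28), as were all 35 G2/M genes. More dividing cells may contribute as well, and this stays open. If they were the cause, the pluripotency median would not exceed that of the G2/M list. It did so by 0.41, past the bound written against that cause, but with a bootstrap range from 0.02 to 0.91. That range is over genes and leaves out the spread between arrays, and the design cannot separate the cluster from its 1 array.

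Probe sets of the cluster C microRNAs fell by 1.41 to 2.96 from day 4 to day 8 without SKO and not with SKO, where they differed by 0.07 to 1.09. With SKO they also rose, at low values, on arrays without cluster C. Mir302c went from 1.96 to 2.64 with blank virus and from 1.70 to 3.08 with cluster B, and Mir302d from 2.07 to 2.98 and from 2.19 to 2.85. The values with SKO therefore need not read the virus alone. All 5 falls without SKO are lower bounds, as at day 8 the probe sets lay under the lower quartile of that array (3.60), Mir302b at 2.86 and Mir302d at 3.03. Mir367 (2.02), Mir302a (2.11) and Mir302c (2.32) were also within the range of arrays without cluster C, which reached 2.13, 2.55 and 3.08. A loss of signal from small RNA probe sets on the day 8 array would lower the others too, and the median change of 277 other microRNA probe sets was 0.04, or 0.07 for the 148 at least as bright at day 4. Fewer cells carrying any of the viruses would lower cluster B probe sets too. Without SKO, Mir363 changed by -0.90, where 5% of other microRNA probe sets were below -0.65. Mir20b went from 3.60 to 2.35, Mir19b-2 from 2.89 to 1.87 and Mir106a from 2.98 to 2.28, but Mir92-2 from 3.57 to 3.71. With SKO, Mir363 changed by -0.23. The falls with both clusters go with fewer cells carrying any of the viruses at day 8 without SKO. That is a hypothesis from a few dim probe sets on single arrays. The clusters were in separate cultures, so a loss of cells carrying cluster C alone would need no change in cluster B probe sets. Neither that nor silencing of the virus was tested.

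Interferon genes with SKO and cluster B had a median of -0.67 against blank virus at day 4 and 0.29 at day 8. A high interferon level on the blank virus array would lower cluster C alike, and its median of -0.28 was 42.2% of that with cluster B. The bootstrap range over genes, 22.4% to 57.6%, leaves out the spread between arrays, and without SKO the list was at -0.44 with cluster B at day 8 against -0.07 with blank virus, so this stays open. Without the day 4 array of cluster B the list median was 0.19, and without the blank virus array of that day 0.10. Whether the array or the condition differed cannot be told apart with 1 array for each.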

How the results depend on the processing

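The cluster effects free to differ between days were chosen after seeing the data; the other settings were planned. The cause was not tested for any shift below. Fitted per arm, cluster B with SKO called 1 gene and the day without SKO 1003. The additive fit called 0 genes for cluster B, cluster C and their difference with SKO, and 5890 for SKO at day 4, and turned Krt7 in SKO at day 4 to 0.27 and Chml in cluster B without SKO to 0.02. With a trend and robust empirical Bayes, cluster C with SKO called 14, the day with SKO 2882, the day without SKO 2921 and their difference 1346. Among genes above the median gene, cluster B with SKO called 0, cluster C 1, their difference 0, the day without SKO 2731 and the difference of days 1012. With every probe set, cluster B with SKO called 1 and the difference of clusters 0. At 1.5-fold or more, the counts were 2088 and 2745 for SKO at days 4 and 8, and 972 and 830 for the day with and without SKO. With effects free to differ between days, cluster B called 0 and 0, and cluster C 0 at day 4 and 18 at day 8. All 13 gene counts and 13 list counts stayed within 1.5 times of the reported count with the mean over probe sets. With an estimated correlation, 0 lists passed in every comparison. With SKO, cluster B had 4 lists after quantile normalization and 4 among brighter genes, and the difference of clusters 5 with equal medians.

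Leaving out 1 array assumes that a condition left without an array varies like the others. The gene counts ran from 0 to 2 for cluster B with SKO, 0 to 18 for cluster C and 0 to 13 for their difference, and without SKO from 0 to 3 for cluster C and 0 to 2 for the difference of clusters. They ran from 0 to 5 for the interaction of cluster C, 2178 to 3730 and 3145 to 5131 for SKO at days 4 and 8, 655 to 1611 and 534 to 1572 for the day with and without SKO, and 230 to 306 for their difference. The list counts ran from 2 to 8 for cluster B with SKO, 5 to 12 for cluster C and 4 to 10 for their difference; without SKO from 0 to 2 for cluster B, 0 to 2 for cluster C and 0 to 3 for their difference; and from 0 to 7 and 5 to 11 for the interactions of cluster B and C. Medians changed sign for interferon (-0.58 to 0.19), G1/S (-0.03 to 0.28), G2/M (-0.11 to 0.19) and keratinocyte genes (-0.06 to 0.25) with cluster B and SKO. With cluster C and SKO they did for muscle (-0.25 to 0.02), keratinocyte (-0.06 to 0.37), G1/S (-0.01 to 0.39) and G2/M genes (-0.15 to 0.38). They also did for G1/S genes between the clusters with SKO (-0.06 to 0.28), for keratinocyte (-0.03 to 0.38) and G2/M genes (-0.11 to 0.43) in the interaction of cluster C, and for epithelial genes with SKO at day 4 (-0.07 to 0.11). Among named genes, Tomm5 with cluster B and SKO ran from -0.04 to 2.04 and Chml with cluster B and no SKO from -1.87 to 0.02. The test of microRNA seed sites in 3' untranslated regions was not run.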

Other observations

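Median differences between viruses of the same arm and day were compared among the 21 lists, over both arms and days. The largest single one was in the pluripotency list, at 0.77 for cluster C minus blank virus with SKO at day 8. The lowest of that list was -0.22, for cluster C minus cluster B without SKO at day 4. Interferon response genes had the widest range. It ran from -0.67 (cluster B minus blank virus) to 0.42 (cluster C minus cluster B), both with SKO at day 4. Both ends use the same array, that with SKO and cluster B at day 4. Against the mean of all arrays, the list was at -0.61 there. It was at 0.11 with blank virus and -0.23 with cluster C, also with SKO at day 4. In the interferon list, the day effect with SKO minus that without had a median of 0.82 (32 of 34 above 0, limma's camera adjusted p = 1.85e-13 at the preset correlation, and adjusted p = 0.277 with an estimated correlation), with 6 genes past the threshold, among them Ddx60 (1.87 ± 0.41). By virus, that median was 0.24 with blank virus, 1.68 with cluster B and 0.61 with cluster C.

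Inflammatory genes moved apart. Saa3, an acute-phase gene, was higher with SKO at day 8 by 3.41 ± 0.19 and the chemokine gene Ccl8 by 1.98, while Cxcl12 was lower by the same fit (-2.38) and Cxcl5 too (-1.71). The endothelial receptor gene Tek was higher with SKO by 3.87 at day 4 and 3.58 at day 8, and Erg was lower (-0.62 and -1.07). In the p53 list, Perp, also a desmosome gene, was 2.0 higher at day 8, and Igfbp5 was -2.54.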
